A study of Talinum fruticosum with 24 samples.

How the data were processed

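RNA sequencing was carried out on mature leaves of Talinum triangulare, listed in the labels under the name Talinum fruticosum, which can switch between C3 photosynthesis and crassulacean acid metabolism (CAM). Per the labels' protocols, polyadenylated RNA was made into TruSeq v2 libraries, a kit that does not mark strand. The 24 libraries fall into 8 groups of 3 biological replicates per the labels and the design text: leaves after 12 d of drought (photosynthetic mode CAM) or after 12 d of drought and 2 d of re-watering (mode reC3), each at the middle of the day (MD, zeitgeber time 6 h), the end of the day (ED, 12 h), the middle of the night (MN, 18 h) and the end of the night (EN, 24 h). Per the labels, the MD and MN libraries were taken over from an earlier series and the ED and EN libraries were new. A difference between MD or MN and ED or EN therefore also compares both sets of libraries, while differences between modes at 1 time, between MN and MD, and between EN and ED stay within 1 set.

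The raw read counts were deposited by the authors as 1 table of 22079 Arabidopsis thaliana gene identifiers, each listed once, with no scaling per the file headers. Per the submitters' processing notes, CASAVA 1.8.2 and the Arabidopsis annotation TAIR10 were used. The aligner and the counter are not given in the sources used here. Reads of a Talinum transcript were thus assigned to Arabidopsis identifiers, and where Arabidopsis has paralogs a transcript's reads can be shared among them or several transcripts can fall on 1 identifier, so values of single members of gene families are uncertain. A further 40 columns of values in the table were not used. No genome of Talinum was used, so no positions are given.

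Counts per library totalled 4310225 to 8756145. Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr kept 14065 genes, libraries were scaled with TMM factors, and the robust quasi-likelihood test was fitted to all 24 libraries with a mean per group, so that all groups share an estimate of the spread (common biological coefficient of variation 0.196). Every adjusted p in the text comes from this test with Benjamini-Hochberg adjustment over the genes tested, unless a gene list is named, and calls were made at 0.05. Results were CAM minus reC3 at each of the 4 times, the average of these 4 differences, the interaction (whether the difference between modes differs between times), any difference between times within each mode, and MN minus MD and EN minus ED within each mode. Standard errors (SE) are the log2 fold change over the square root of its F statistic. Levels are in CPM, counts scaled by TMM-adjusted library totals, as mean ± SD over 3 libraries. A group without a count was set to a floor of 3 counts over the group, 0.117 to 0.177 CPM, and folds against it are given as lower bounds. With 1 to 3 counts the ratio is given with an exact 95% counting interval. For genes of the average with 3 counts or fewer in any group, whose fitted fold depends on the prior count, the ratio of TMM-scaled counts pooled over the 12 libraries of each mode is given with such an interval. Floors and intervals cover counting error only.

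Genes were grouped in 19 lists by Arabidopsis identifier: CAM carbon cycle, starch synthesis, starch degradation, ABA metabolism and signalling, dehydration response, osmoprotectants and sugars, circadian clock, light reactions, Calvin-Benson cycle, photorespiration, nitrogen assimilation, heat shock and chaperones, senescence and chlorophyll breakdown, cell wall growth, wax and cuticle, and markers of dividing cells, guard cells, vascular tissue and epidermis. They hold 359 entries, of which 281 were in the table and 269 were tested. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 and again with a correlation estimated from the data, each adjusted over the 19 lists. Counts of members are also given adjusted over the list alone. Members expressed in other leaf tissues as well were not excluded from the marker lists.

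Genes are named by a rule. For the average these are the 10 largest changes in each direction with adjusted p under 0.05, at least 10 CPM in the higher mode and the same direction at all 4 times. For each time and each contrast between times they are the 3 largest in each direction with at least 10 CPM in the higher group and no overlap of the libraries. For the interaction they are the 6 smallest p with at least 10 CPM. From each list up to 4 members with the smallest adjusted p are named, and from the CAM carbon cycle every member that changed in the average at 10 CPM or more. The groups, lists, tests, naming rule and most alternative settings were fixed before the data were examined.

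Alternative settings fixed in this way were DESeq2 1.42.0, RLE scaling, no filter on low counts (16869 genes), adjusted p under 0.01 with a 2-fold change, the replicate number as a block, the 6 libraries of the compared groups alone, camera with an estimated correlation, and leaving out each library in turn. Scaling by library totals alone, leaving out reC3 MD replicate 3 together with reC3 EN replicate 1 (in each group the library with the lowest correlation with its partners), and leaving out EN were added after the data had been seen. For tests over several contrasts at once the stricter threshold was adjusted p under 0.01 without a fold. The test was checked on simulated counts with 200 changed genes. For genes changed in CAM at all 4 times it recovered 92.7% of the 2-fold and 100% of the 4-fold changes in the average (13798 genes tested) and 61.5% and 92.9% at MD. For genes changed at EN alone it recovered 52.6% and 91.8% at EN (13819 genes tested) and 27.8% and 83.7% in the interaction. False calls made up 2.68 to 4.10% of the calls. Apart from the 200 changed genes, the simulated means were the same in all groups. These rates may therefore not carry over to the data, in which 64.8% of the genes changed in the average.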

Results

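Transcript levels were measured in mature leaves of Talinum triangulare, a plant that shifts from C3 photosynthesis to CAM, in which CO2 is taken up at night and stored as malic acid, when water is short. The design asks which genes differ between leaves in CAM after 12 d of drought and leaves returned to C3 photosynthesis by 2 d of re-watering (reC3), and how these differences change over the day and night. Each of the 8 groups (2 modes at MD, ED, MN and EN) held 3 biological replicates. No group held leaves that were never droughted. A rise or fall in CAM therefore cannot be told apart from an opposite change on re-watering, nor photosynthetic mode from water supply. Libraries held 4310225 to 8756145 counts on 14733 to 15367 genes, and 14065 genes were tested. The mean correlation of a library with its partners, across genes, was 0.941 to 0.986, lowest in reC3 EN replicate 1 (0.941) and replicate 2 (0.952). In reC3 MD, the 10 most abundant genes took 12.6% of the counts of replicate 3 against 23.5% and 20.3% in replicates 1 and 2. No pair of replicates differed by as little as sampling noise (chi-square per degree of freedom 4.13 to 138). TMM factors ran from 0.608 (reC3 EN replicate 1) to 1.43 (reC3 ED replicate 2).

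Averaged over the 4 times, the genes with the largest rises in CAM included myo-inositol oxygenases, which open the inositol ring to glucuronic acid, and those with the largest falls included germin-like proteins of the cell wall. MIOX1 (AT1G14520) averaged 416 CPM in CAM and 4.42 CPM in reC3 over 12 libraries each, a log2 fold change of 5.87 ± 0.337 (SE; adjusted p = 8.92e-12, edgeR quasi-likelihood test). MIOX4 (AT4G26260) rose by 5.19 ± 0.445, and by 6.23 without reC3 EN replicate 1. The DnaJ-domain chaperone AT1G80920 rose by 5.39 ± 0.158 (809 against 34.9 CPM; adjusted p = 2.56e-16), and OXS3 (AT5G56550, oxidative stress 3) by 5.06 ± 0.253. AT3G03170 (5.17 ± 0.299) and AT4G26288 (4.60 ± 0.294) also rose. The other 4 rises had a reC3 group with 3 counts or fewer and are given as ratios of the counts pooled over 12 libraries per mode. The ratio was 80.3 for the glycosyl hydrolase AT1G02310 (95% counting interval 43.5 to 168), with 828 counts in CAM and 10 in reC3, and 70.6 for MIOX2 (AT2G19800; 59.8 to 83.9). For the terpenoid cyclase AT3G29410 it was 30.2 (21.9 to 42.9), and for EDL3 (AT3G63060), an F-box protein of abscisic acid (ABA) signalling, 19.9 (15.6 to 25.7).

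Among the falls, GER3 (AT5G20630) averaged 1.38 CPM in CAM and 528 CPM in reC3 (log2 fold change -7.55 ± 0.631, adjusted p = 3.38e-09, edgeR), and GER1 (AT1G72610) changed by -7.26 ± 0.660. Without reC3 EN replicate 1, GER3 was at -6.81 and GER1 at -6.62. The germin-like GL22 (AT1G02335), with 6 counts in CAM and 806 in reC3, was lower by a ratio of 138 in the pooled counts (95% counting interval 63.3 to 378), and GLP10 (AT3G62020), with 10 and 792 counts, by 81.6 (44.2 to 171). The GDSL lipases AT4G28780 and AT5G33370 changed by -6.65 ± 0.359 and -6.12 ± 0.338. Enzymes that act on the cell wall were also among them, with the pectate lyase AT1G67750 lower by a ratio of 77.4 in the pooled counts (57.1 to 108) and GH9B8 (AT2G32990), of the glycosyl hydrolase family that holds the cellulases, at -5.999 ± 0.361. DFR (AT5G42800), dihydroflavonol reductase of anthocyanin synthesis, changed by -6.30 ± 0.659 and the cytochrome P450 CYP86A7 (AT1G63710) by -6.26 ± 0.327. Without CAM ED replicate 3, GH9B8 was at -6.74 and CYP86A7 at -6.87. In the average 9112 of the 14065 genes changed (64.8%), 4536 higher and 4576 lower in CAM. With at least a 2-fold change 804 were higher and 1909 lower. Of the genes tested at each time, 654 were higher in CAM at all 4 times (29.9 expected of independent lists) and 1106 lower (43.0 expected). The calls at the 4 times came from 1 fit with a shared estimate of the spread. They are therefore not independent, and these expectations may be too low.

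Genes of the CAM carbon cycle, which fix CO2 into malate at night and release it by day, rose and fell in the average: 13 of 28 rose and 5 fell (list adjusted p = 0.0529, camera with a preset correlation; adjusted p = 0.300 with an estimated correlation). PPC1 (AT1G53310) and PPC2 (AT2G42600), both phosphoenolpyruvate (PEP) carboxylases, the enzyme of the nightly fixation, rose by 3.32 ± 0.188 (adjusted p = 1.35e-12, edgeR) and 3.51 ± 0.187. PPCK1 and PPCK2, the kinases that activate PEP carboxylase, rose by 1.51 ± 0.167 and 1.42 ± 0.148, and PPDK, which regenerates PEP from pyruvate, by 1.56 ± 0.278. Smaller rises were found for the malic enzymes, which release CO2 from malate, NADP-ME1 (0.64), NADP-ME2 (0.75), NADP-ME4 (0.79) and NAD-ME1 (0.37), for the malate channels ALMT4 (0.56) and ALMT6 (0.67), and for the pyruvate transporter BASS2 (0.84). The PEP transporters PPT1 (-0.78) and PPT2 (-1.85 ± 0.133), NAD-ME2 (-0.23) and RP1, the regulator of PPDK (-0.29), fell. RP1 was higher in CAM at ED (1.08) and lower at MN (-1.02) and EN (-1.27), and without EN it averaged 0.036 (adjusted p = 0.684, edgeR). The plastid glucose-phosphate transporter GPT1 averaged -0.56 ± 0.237 (adjusted p = 0.0439, edgeR), although its mean level was higher in CAM (341 against 222 CPM). This call was lost in 21 of the 24 fits that left out 1 library each, without a filter on low counts (adjusted p = 0.0590) and under library totals alone (adjusted p = 0.0637). GPT1 differed most within reC3 MD, with 70.6, 515 and 944 CPM in replicates 1, 2 and 3, and was at -0.69 without replicate 1 (adjusted p = 3.84e-06) and at -0.36 without replicate 3 (adjusted p = 0.126).

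**Figure D1:**
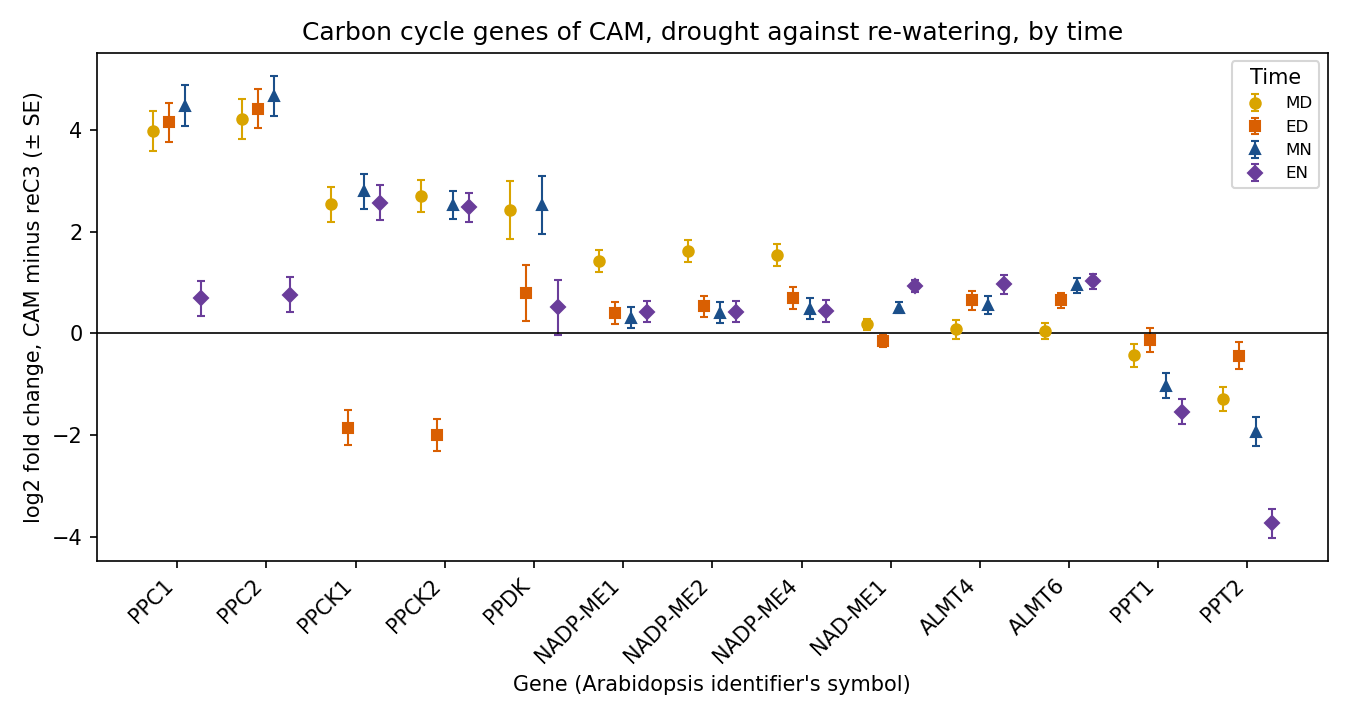
Log2 fold change (CAM minus reC3, ± SE, 3 libraries per group) of 13 genes of the CAM carbon cycle at MD, ED, MN and EN. PPC1 lies at 3.98, 4.14 and 4.47 at MD, ED and MN and at 0.69 at EN, while PPCK1 lies at -1.86 at ED and between 2.53 and 2.79 at the other times.

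Both PEP carboxylases were high in CAM throughout and low in reC3 except at EN. PPC1 stood at 7543 ± 1090 CPM in CAM and 480 ± 99.6 CPM in reC3 at MD (SD, n = 3 libraries each), 11031 ± 659 and 625 ± 105 at ED, and 14119 ± 2152 and 636 ± 101 at MN. At EN it stood at 8776 ± 1141 CPM in CAM, and the reC3 libraries spread from 1929 CPM in replicate 1 to 4979 CPM in replicate 3 and 9382 CPM in replicate 2. Its log2 fold change was 3.98 ± 0.388 at MD (adjusted p = 5.06e-08, edgeR), 4.14 ± 0.391 at ED, 4.47 ± 0.397 at MN and 0.69 ± 0.346 at EN (adjusted p = 0.0961). PPDK spread in the same way over the reC3 libraries at EN, with 2268, 13256 and 28715 CPM in replicates 1, 3 and 2. It rose at MD (2.43 ± 0.572) and MN (2.52 ± 0.574) and measured 0.79 at ED and 0.51 at EN, and its interaction was not past the threshold (adjusted p = 0.0552, edgeR). PPCK1 rose at MD (2.53 ± 0.346), MN (2.79 ± 0.342) and EN (2.57 ± 0.338) and fell at ED (-1.86 ± 0.343, adjusted p = 0.000171, edgeR). The 3 NADP-malic enzymes rose most at MD, by 1.42 to 1.62. PPC1 with PPC2, PPCK1 with PPCK2 and the malic enzymes are paralogs, and how reads were shared among them is uncertain.

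**Figure D2:**
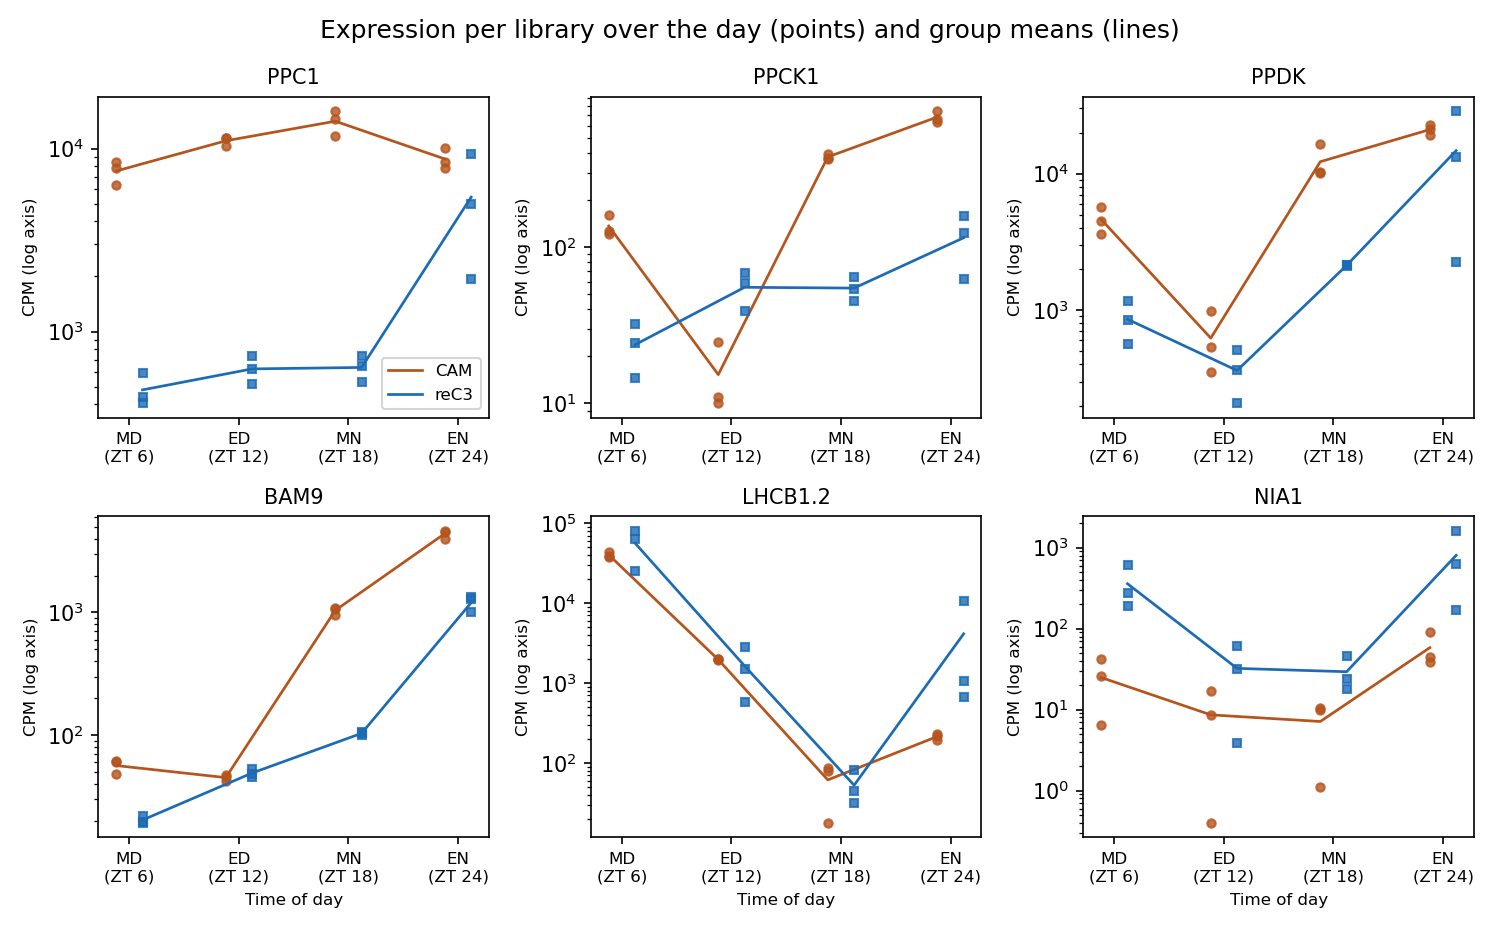
CPM on a log axis of PPC1, PPCK1, PPDK, BAM9, LHCB1.2 and NIA1 at MD, ED, MN and EN in CAM and reC3, each point a library and each line joining the group means. At EN the reC3 libraries spread from 1929 to 9382 CPM for PPC1 and from 679 to 10641 CPM for LHCB1.2.

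Starch genes went both ways in the average. In starch synthesis 4 of 12 rose and 4 fell (list adjusted p = 0.632, camera), the falls being PGM1 (-1.44 ± 0.101) and PGI1 (-1.56 ± 0.124), which pass carbon from the Calvin-Benson cycle to starch, and the starch synthases SS2 (-1.02) and SS3 (-1.03). In starch degradation 7 of 18 rose and 8 fell (list adjusted p = 0.523), against 7 and 6 under library totals alone and without any 1 of 5 libraries (CAM ED replicate 2, CAM MN replicate 2, reC3 EN replicates 2 and 3, and reC3 MD replicate 3). BAM9, of the beta-amylase family, rose by 1.64 ± 0.0802 and the alpha-amylase AMY3 by 1.79 ± 0.114, SEX1, the glucan water dikinase, rose by 0.94 ± 0.116, and PWD, which acts after SEX1, fell (-1.29 ± 0.145). By time, SEX1 was at 2.02 at MD, 2.00 at ED, 0.51 at MN and -0.75 at EN.

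Among the stress lists, genes of osmoprotectants and of ABA mostly rose in CAM in the average. At ED they went both ways, with 7 of 17 osmoprotectant genes higher and 5 lower. Of ABA genes 5 of 26 were higher and 5 lower at ED (3 and 5 adjusted over the list alone). In the dehydration response 1 of 8 was higher and 4 were lower at ED. Of osmoprotectants and sugars, 12 of 17 rose and 5 fell (list adjusted p = 0.0215, camera with a preset correlation; adjusted p = 0.300 with an estimated correlation). SIP1, of the raffinose synthase family, rose by 3.95 ± 0.210, the trehalose-phosphate synthase family members TPS9 and TPS10 by 1.72 each, and P5CDH, of proline breakdown, by 1.86. Of ABA metabolism and signalling, 18 of 26 rose and 7 fell (list adjusted p = 0.0558; adjusted p = 0.581 with an estimated correlation), with rises of the protein phosphatases HAI2 (2.08 ± 0.147) and PP2CA (1.56 ± 0.123) and falls of the ABA hydroxylase CYP707A2 (-3.12 ± 0.125) and the receptor PYR1 (-2.18 ± 0.142). In the dehydration response 4 of 8 rose and 2 fell (list adjusted p = 0.291), with COR47 at 2.12, ERD15 at 1.51, RD20 at 1.28 and RD22 at -2.59. In heat shock and chaperones 4 of 12 rose and 4 fell (list adjusted p = 0.821), with HSP21 at 2.27, HSFA2 at 1.62, HSP101 at -2.45 and HSP17-4 at -1.30. In senescence and chlorophyll breakdown 2 of 7 rose and 3 fell (list adjusted p = 0.924), and NAP, a transcription factor of leaf senescence, rose by 2.93 ± 0.310, while SAG12 (-0.76), PPH (-0.53) and PAO (-0.49) fell. By time, PPH was at 1.38 at MD, -1.46 at ED, -1.98 at MN and -0.07 at EN. In the circadian clock 7 of 22 rose and 4 fell (list adjusted p = 0.259), with TOC1 at 1.14 ± 0.0695, LNK1 at 1.24, RVE8 at 0.65 and RVE6 at 0.59.

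Among genes of photosynthesis and nitrogen uptake, more fell than rose in CAM in the average. For the light reactions the falls lay mostly at MD and EN. At ED 7 were higher and 1 lower, and at MN 1 and 2 (1 and 1 adjusted over the list alone). In the Calvin-Benson cycle 5 were higher and none lower at ED, and none passed at MN. Neither list passed at ED (adjusted p = 0.103 and 0.0611) or MN (0.906 and 0.893, camera with a preset correlation). Of the light reactions, 2 of 31 rose and 19 fell (2 and 20 adjusted over the list alone; list adjusted p = 0.0513, camera with a preset correlation; adjusted p = 0.815 with an estimated correlation). The photosystem subunits PSBY (-1.75 ± 0.164), PSBS (-1.25 ± 0.141) and PSAF (-1.13 ± 0.177) and the antenna protein LHCA3 (-1.27 ± 0.219) fell. In the Calvin-Benson cycle 2 of 14 rose and 6 fell (list adjusted p = 0.650), with PRK at -0.79, GAPB at -0.74, RPI3 at -0.89 (-0.39 without EN, adjusted p = 0.0954) and the triose-phosphate isomerase PDTPI at 0.75. In photorespiration 2 of 17 rose and 4 fell (list adjusted p = 0.824), with BOU at -2.18, the catalase CAT2 at -1.25, AGT1 at 0.80 and HPR1 at 0.56. In nitrogen assimilation 3 of 6 fell and none rose (list adjusted p = 0.291): the nitrate reductases NIA1 (-2.89 ± 0.507) and NIA2 (-2.87 ± 0.523) and the nitrate transporter NRT1.1 (-1.63 ± 0.118). GDH2 was at 0.15 (adjusted p = 0.154, edgeR) and at -0.23 without EN (adjusted p = 0.0140). NIA1 differed within reC3 EN, with 1622, 170 and 623 CPM in replicates 1, 2 and 3.

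In cell wall growth 1 of 9 rose and 7 fell (median log2 fold change -2.23; list adjusted p = 0.0215, camera with a preset correlation; adjusted p = 0.579 with an estimated correlation), with the cellulose synthase CESA5 at -2.23 ± 0.0985 and the wall-loosening expansins EXPA4, EXPA5 and EXPA6 at -2.49, -3.94 and -3.55. Of the markers of dividing cells, 7 of 8 fell and none rose (list adjusted p = 0.0215; adjusted p = 0.300 with an estimated correlation). MCM7 and MCM2, of the replicative helicase, were lower by ratios of 19.2 (95% counting interval 13.3 to 28.5) and 28.2 (20.4 to 40.1) in the pooled counts, the cyclin CYCB1.1 by 2.55 (1.93 to 3.40), and the cyclin CYCD3.1 was at -2.83. The list median was -2.47 with MCM2, which had no count in CAM at EN, at the floor of that group. Of the vascular markers, 1 of 9 rose and 7 fell (list adjusted p = 0.0215; adjusted p = 0.300 with an estimated correlation), with the cellulose synthases of the secondary wall IRX1, IRX3 and IRX5 at -1.81, -1.75 and -1.87 and the sugar transporter SWEET11 at 1.76. In wax and cuticle 3 of 14 rose and 8 fell (list adjusted p = 0.468), with SHN1 at -2.46, WSD1 at -1.89, KCS2 at 1.59 and CER3 at 1.44. Of the epidermis markers, 4 of 5 fell and none rose (list adjusted p = 0.0607; adjusted p = 0.300 with an estimated correlation), with LACS2 at -3.24 and ANL2, PDF2 and FDH between -0.35 and -0.23 (FDH at -0.14 without EN, adjusted p = 0.0930). By time, ANL2 was at -0.83 at MD, -0.36 at ED, -0.13 at MN and 0.26 at EN. Of the guard cell markers, 1 of 6 rose and 4 fell (2 and 4 adjusted over the list alone; list adjusted p = 0.376), with the potassium channel GORK at 1.82 and KAT2, MYB60 and HT1 at -0.94, -0.88 and -0.79.

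**Figure D3:**
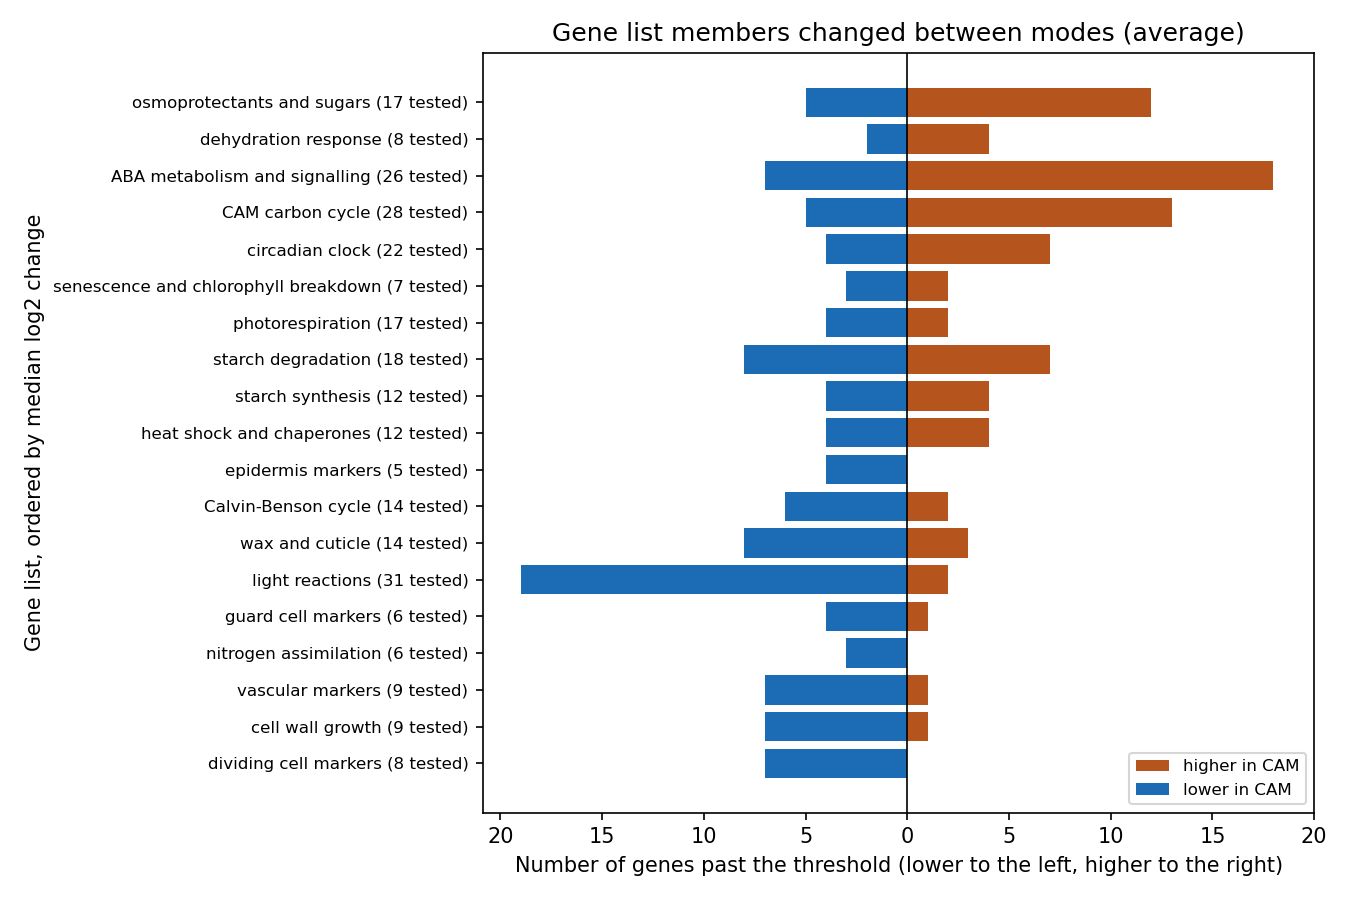
Number of tested members of each of the 19 gene lists that were higher or lower in CAM in the average over 4 times at adjusted p under 0.05. Light reactions (2 higher, 19 lower of 31) and ABA metabolism and signalling (18 higher, 7 lower of 26) lie on opposite sides.

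For the other 17 lists the counts of the average were the same when adjusted over the list alone. So were list counts of single contrasts given without such a value, unless marked as adjusted over all genes or given for an alternative setting. The calls of the light reactions, ABA and CAM carbon cycle lists in the average lay near the threshold and were past it under RLE scaling (adjusted p = 0.0478 each, camera with a preset correlation). With an estimated correlation no list passed in any of the 9 contrasts (171 list tests, 19 at an unadjusted p under 0.05 with camera, lowest adjusted p 0.0829).

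At MD, 6190 genes differed between modes, 3189 higher and 3001 lower in CAM. The larger share turned to lower under RLE scaling (2827 higher and 3196 lower), DESeq2 (2874 and 3225) and library totals alone (2703 and 2812), and with at least a 2-fold change 1210 were higher and 1979 lower. EDL3, with 421 counts in CAM and 2 in reC3, had a ratio of 240 (95% counting interval 66.1 to 1990), ELIP1, an early light-induced protein, rose by 7.24 ± 0.970 (adjusted p = 7.13e-06, edgeR) and MIOX1 by 6.51, and without reC3 MD replicate 3 they rose by 8.05 and 7.62. The ribonuclease AT1G14210 was at least 123-fold lower (187-fold without reC3 MD replicate 3) and GLP10 at least 61.1-fold lower in CAM, and GER3 changed by -9.32. Of the CAM carbon cycle 14 genes rose and 2 fell (14 and 2 also adjusted over the list alone; list adjusted p = 0.00333, camera with a preset correlation; adjusted p = 0.0946 with an estimated correlation). Of starch degradation 12 rose and 2 fell (13 and 2 adjusted over the list alone; list adjusted p = 0.00119; adjusted p = 0.229 with an estimated correlation), SEX1 rising by 2.02 and BAM9 by 1.47. Starch synthesis had 7 of 12 higher and 3 lower (7 and 4 adjusted over the list alone, median 0.62). That list did not pass (adjusted p = 0.185, camera with a preset correlation, and 0.379 with an estimated correlation). Of the cell wall growth genes 8 of 9 fell and none rose (9 fell adjusted over the list alone; list adjusted p = 0.000113; adjusted p = 0.229 with an estimated correlation). Of the light reactions 1 rose and 10 fell (list adjusted p = 0.0183; adjusted p = 0.687 with an estimated correlation), but 6 fell without reC3 MD replicate 1, 17 without reC3 MD replicate 3, and 21 without reC3 MD replicate 3 and reC3 EN replicate 1, libraries left out after the data had been seen. In the clock 7 rose and 1 fell (list adjusted p = 0.0433; adjusted p = 0.325 with an estimated correlation), and 12 rose without the latter pair of libraries.

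At ED, 6388 genes differed, 3025 higher and 3363 lower in CAM. The dormancy-associated AT1G54070 rose by 6.65 ± 0.906 (adjusted p = 8.54e-06, edgeR), AT1G80920 by 6.28 ± 0.310 and AT3G03170 by 5.998. AT2G25625, with 1 count in CAM and 580 in reC3, was lower by a ratio of 598 (95% counting interval 107 to 23653), allantoinase, ALN, which breaks down allantoin of purine turnover, changed by -6.86 and GER3 by -6.82. Without reC3 ED replicate 1, AT3G03170 was at 5.38 and GER3 at -5.90, and without CAM ED replicate 3, ALN was at -7.79. Of the photorespiration genes 10 of 17 were higher and 2 lower, AGT1 rising by 2.14 and HPR1 by 1.05, and of the heat shock list 7 of 12 were lower and none higher. Neither list passed (list adjusted p = 0.0611 and 0.0878, camera with a preset correlation; adjusted p = 0.624 for both with an estimated correlation). Of photorespiration 3 were higher without CAM ED replicate 1 or reC3 ED replicate 2 and 4 without reC3 ED replicate 3, and without the last 4 heat shock genes were lower and 1 higher. Cell wall growth had 6 of 9 lower (list adjusted p = 0.0148, camera with a preset correlation; adjusted p = 0.559 with an estimated correlation). Scaling by library totals alone shifted the median of all genes to -0.21 and gave 1766 higher and 4098 lower genes. Under it the CAM carbon cycle list turned from 10 higher and 7 lower (list adjusted p = 0.268) to 5 higher and 9 lower.

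At MN, 5426 genes differed, 2542 higher and 2884 lower in CAM. AT5G50360 was at least 83.1-fold higher in CAM, MIOX1 rose by 7.60 ± 0.704 (adjusted p = 8.92e-08, edgeR) and MIOX2 by 7.48, with its reC3 counts at MN in replicate 3 alone. CYP708A2, a cytochrome P450 of triterpene synthesis with 3 counts in CAM and 663 in reC3, was lower by a ratio of 243 (95% counting interval 82.7 to 1181), and DFR and CYP86A7 changed by -7.56 and -7.05 (CYP86A7 by -7.68 without CAM MN replicate 2). Of ABA genes 16 rose and 6 fell (17 and 7 adjusted over the list alone; list adjusted p = 0.00508, camera with a preset correlation; adjusted p = 0.449 with an estimated correlation), HAI2 rising by 2.58 and PP2CA by 2.25. Of the CAM carbon cycle 10 rose and 4 fell (10 and 5 adjusted over the list alone; list adjusted p = 0.0492; adjusted p = 0.368 with an estimated correlation). Of osmoprotectants and sugars 11 rose and 4 fell (list adjusted p = 0.0229; adjusted p = 0.368 with an estimated correlation), SIP1 rising by 5.40. Cell wall growth had 1 of 9 higher and 4 lower (3 and 4 adjusted over the list alone, median -0.64). This list did not pass at MN (adjusted p = 0.558, camera with a preset correlation, and 0.976 with an estimated correlation). Library totals alone moved the share of higher genes from 46.8% to 38.0%.

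At EN, 7501 genes differed, 3389 higher and 4112 lower in CAM. The cystathionine beta-synthase domain protein AT1G15330 was at least 168.5-fold higher in CAM, ECP63, a late embryogenesis abundant protein, at least 59.8-fold, and MIOX2 had a ratio of 270 (95% counting interval 74.5 to 2236). GER3, GER1 and the desaturase FAD5 changed by -8.87, -8.82 and -8.57 (adjusted p = 4.02e-06 for FAD5, edgeR), and by -5.89, -6.23 and -6.92 without reC3 EN replicate 1. GER1 was at -9.62 without CAM EN replicate 1. Of the light reactions 27 of 31 fell and none rose (28 adjusted over the list alone), with a median log2 fold change of -1.75 (list adjusted p = 1.25e-05, camera with a preset correlation; adjusted p = 0.530 with an estimated correlation). LHCA4 changed by -5.98, LHCB3 by -4.35 and LHCB1.2 by -4.26 ± 0.873. LHCB1.2 differed within reC3 EN, with 10641, 679 and 1064 CPM in replicates 1, 2 and 3, and without replicate 1 of that group LHCA4 was at -3.89, LHCB3 at -1.86 and LHCB1.2 at -2.02 ± 0.578, and 22 light reaction genes fell, with a median of -1.12. Of starch synthesis 9 of 12 fell and 1 rose, PGM1 changing by -3.08. Of the Calvin-Benson cycle 10 of 14 fell and none rose. For both lists the adjusted p was 0.0152 (camera with a preset correlation), and 0.326 and 0.530 with an estimated correlation. Opposite to ED, 12 of 17 photorespiration genes fell and none rose (adjusted over all genes, median -0.89). Without reC3 MD replicate 3 and reC3 EN replicate 1, 9 fell (median -0.46). Under library totals alone 10 fell and 2 rose. Of osmoprotectants and sugars 12 of 17 rose and 4 fell (list adjusted p = 0.00230; adjusted p = 0.326 with an estimated correlation), SIP1 rising by 6.15, and the senescence regulator NAP rose by 4.97 (5.75 without reC3 EN replicate 2). Library totals alone shifted the median of all genes to 0.21 and turned the split to 4541 higher and 2742 lower genes, with 26 light reaction genes lower.

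Whether the difference between modes differs between times was tested as an interaction, and 6583 genes passed (46.8%). Of these, 1452 were higher in CAM at 1 time and lower at another. Between MD or MN and ED or EN, a change over the day cannot be told apart from a mode difference that differs between the sets of libraries. The kelch-repeat protein AT1G67480 stood at 1.94 ± 0.251 CPM in CAM and 28.1 ± 7.96 CPM in reC3 at ED (SD, n = 3 libraries each) but at 354 ± 99.2 and 159 ± 14.8 CPM at EN, with log2 fold changes of -0.38, -3.85, 1.52 and 1.15 at MD, ED, MN and EN (interaction adjusted p = 6.09e-09, edgeR). NHO1, a glycerol kinase, moved from -0.58 at MD to 2.00 at EN, and the repeat protein AT2G39090 from -0.39 at ED to 2.48 at EN. The polyamine oxidase PAO1 changed by -2.07 at MN and -3.63 at EN after 0.35 and 0.71 at MD and ED. At ED the call of PAO1 was lost without CAM ED replicate 2 (0.49, adjusted p = 0.0814, edgeR) and that of AT2G39090 without CAM ED replicate 3 (-0.35, adjusted p = 0.0554) or reC3 ED replicate 2 (-0.35, adjusted p = 0.0570). BAM9 rose by 3.33 at MN, from 103 CPM in reC3 to 1040 CPM in CAM, and measured -0.12 at ED. PREP2, an organellar protease that degrades targeting peptides, rose by 1.56 at MD and fell by 3.66 on the log2 scale at EN. By list, the interaction was past the threshold for 20 of 28 CAM carbon cycle genes (24 adjusted over the list alone), 16 of 18 of starch degradation (18), 25 of 31 of the light reactions (27), 23 of 26 of ABA (25) and 14 of 22 of the clock (15).

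Levels differed between times for 10958 genes in CAM (77.9%) and 10220 in reC3 (72.7%). Of the 8565 genes that differed between times in both modes, 5084 (59.4%) had their highest mean at the same time. Most often the highest mean lay at EN, for 35.0% of the genes in CAM and 36.3% in reC3. Since the MD and MN libraries and the ED and EN libraries came from separate sets, these counts also hold any difference between the sets. They also depend on scaling, as the time of the highest mean was taken from TMM-scaled levels alone. Library totals alone shifted the median of EN minus ED to -0.46 in CAM and -0.97 in reC3. The share of genes highest at EN was not computed under that scaling.

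From MD to MN, genes of the light reactions fell in both modes. In CAM 27 of 31 fell and none rose (28 adjusted over the list alone; list adjusted p = 7.68e-11, camera with a preset correlation; adjusted p = 0.366 with an estimated correlation), LHCB2.2 changing by -9.48 and LHCB1.2 by -9.35. In reC3 28 fell and none rose (28 also adjusted over the list alone; list adjusted p = 6.91e-18; adjusted p = 0.217 with an estimated correlation), LHCB3 and LHCA4 changing by -10.55 each, and by -11.34 and -11.18 without reC3 MN replicate 1. DIC3, a mitochondrial dicarboxylate carrier, fell most in CAM (-9.89 ± 0.489, adjusted p = 2.63e-12, edgeR; -10.52 without CAM MN replicate 1), and AT1G14210 was at least 163-fold lower at MN in reC3 (248-fold without reC3 MD replicate 3). The B-box protein AT1G68190 (7.42), the expansin EXPA14 (6.49) and the wound-responsive AT4G28240 (6.26) rose most in CAM, and urease, URE (6.65), the PLATZ factor AT1G21000 (5.58) and AT4G28240 (5.55) rose most in reC3. Starch synthesis fell at MN in CAM, 10 of 12 against 1 higher (list adjusted p = 0.000201; adjusted p = 0.0829 with an estimated correlation), and in reC3, 7 of 12 against 2 higher (list adjusted p = 0.00828; adjusted p = 0.169 with an estimated correlation). In all 7319 genes changed in CAM (3597 higher and 3722 lower at MN) and 6099 in reC3 (3051 and 3048). Library totals alone shifted the median of all genes to 0.35 in CAM and 0.43 in reC3 and gave 5049 higher and 2321 lower genes in CAM and 5413 and 1555 in reC3.

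From ED to EN, ABA genes rose in CAM, 22 of 26 against 1 lower (list adjusted p = 0.000323, camera with a preset correlation; adjusted p = 0.258 with an estimated correlation). In reC3 11 rose and 1 fell (list adjusted p = 0.0428; adjusted p = 0.474 with an estimated correlation), a direction that turned to 4 higher and 9 lower under library totals alone. Photorespiration genes rose in both modes, in CAM 11 of 17 against 3 lower (list adjusted p = 0.0203; adjusted p = 0.697 with an estimated correlation) and in reC3 16 of 17 (17 adjusted over the list alone; list adjusted p = 5.89e-08; adjusted p = 0.302 with an estimated correlation). Of the light reactions 27 of 31 rose and none fell in reC3 (list adjusted p = 2.30e-06; adjusted p = 0.474 with an estimated correlation), with 19 rising under library totals alone. Without reC3 EN replicate 1, 23 rose and 2 fell in reC3 (24 and 2 when reC3 MD replicate 3 was left out too), and the median went from 1.84 to 1.299 in both cases. In CAM 6 rose and 9 fell (list adjusted p = 0.826). Of the CAM carbon cycle 17 rose and 5 fell in reC3 (17 and 6 adjusted over the list alone; list adjusted p = 0.00749; adjusted p = 0.151 with an estimated correlation), and 11 rose and 9 fell under library totals alone. In CAM 13 of these genes rose and 5 fell (list adjusted p = 0.0794). AT1G18265 (10.08, and 10.70 without CAM ED replicate 2) and AT1G20925 (9.55) rose most in CAM, and the thiamine synthesis enzyme AT5G54770 (-9.40) and AT1G63550 (at least 72.7-fold lower) fell. In reC3 AT1G62190 was at least 403-fold (199-fold without reC3 EN replicate 1) and AT3G10113 at least 281-fold higher, FADA, with 1 count at ED and 2275 at EN, had a ratio of 3093 (95% counting interval 555 to 122220), and AT5G54770 changed by -8.97. Without reC3 EN replicate 1 the ratio of FADA was 1525 and AT5G54770 was at -9.83. GA2OX2, a gibberellin-inactivating oxidase, was at least 61.1-fold lower and FMO1, with 1 count at EN and 461 at ED, was lower by a ratio of 339 (95% counting interval 60.6 to 13422). In all 8956 genes changed in CAM (4432 higher and 4524 lower at EN) and 8150 in reC3 (4096 and 4054). Library totals alone shifted the median of all genes to -0.46 in CAM and -0.97 in reC3 and gave 2648 higher and 6248 lower genes in CAM and 1508 and 8946 in reC3.

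Clock genes cycled strongly in both modes, with all 22 tested differing between times in each mode, and a median amplitude of 5.02 log2 units in CAM and 5.13 in reC3. LHY and CCA1, the morning transcription factors, rose from ED to EN by 9.51 ± 0.252 and 9.51 ± 0.268 in CAM and by 10.28 ± 0.262 and 9.83 ± 0.273 in reC3 (adjusted p = 2.87e-17 for LHY in CAM, edgeR). RVE8 rose by 5.50 and 4.76, and GI, which peaks late in the day, changed by -8.25 in CAM and -7.84 in reC3. From MD to MN the evening gene TOC1 rose by 4.14 and 4.57, and PRR3 and PRR9 changed by -6.58 and -7.43 in CAM and by -7.00 and -6.86 in reC3. LNK2 changed by -6.89 in CAM and RVE1 by 4.47 in reC3. Between modes TOC1 was higher in CAM at all 4 times (0.90 to 1.42). LHY did not pass the test between modes at any of the 4 times (0.59 at ED, adjusted p = 0.0647, edgeR) and reached 2278 to 2575 CPM in the 3 reC3 libraries at EN, whose PPC1 levels lay far apart.

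**Figure D4:**
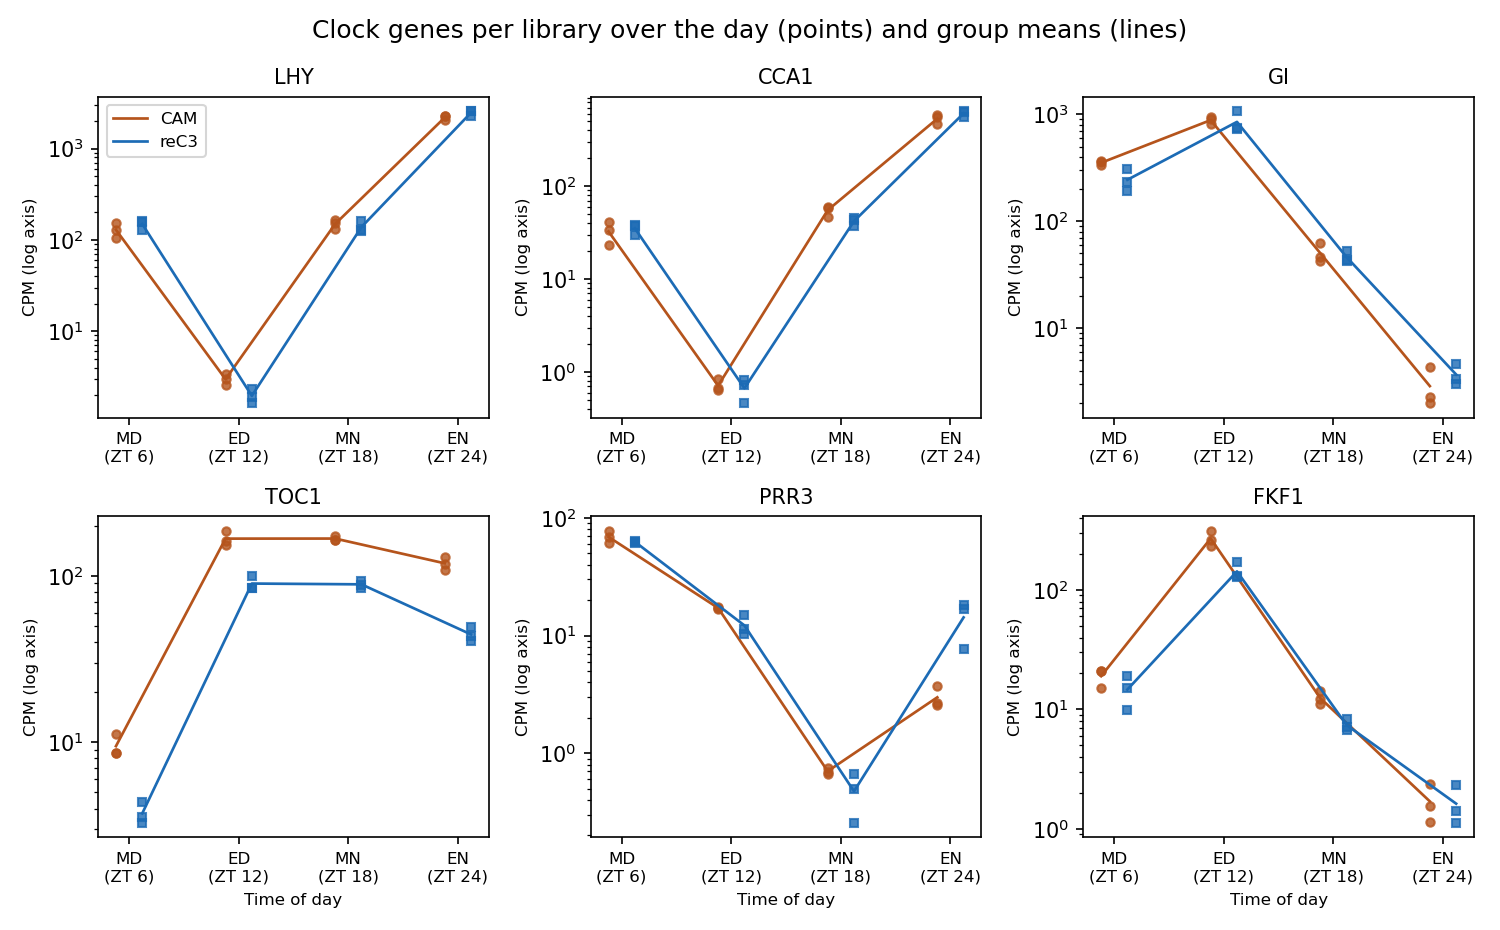
CPM on a log axis of the clock genes LHY, CCA1, GI, TOC1, PRR3 and FKF1 at MD, ED, MN and EN in CAM and reC3, each point a library and each line joining the group means. LHY and CCA1 are highest at EN in both modes, and TOC1 lies higher in CAM at each time.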

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

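The comparison of PPC1, PPC2 and PPDK levels with those of other genes higher in CAM was chosen only after the result was seen. So was the test of a fixed split between PPC1 and PPC2 by mode. The same holds for leaving out reC3 EN replicate 1 with reC3 MD replicate 3 and for leaving out EN. It also holds for scaling by library totals alone and for the bootstrap interval for the paralog pairs. The difference between modes itself differed between times for 6583 genes in the interaction test, where time is in part confounded with the set of libraries. For 1452 genes the difference between modes was past the threshold in opposite directions at a pair of times. Of the 150 named genes, 103 passed the interaction test and 15 went in opposite directions at a pair of times. These were AT1G67480, NHO1, AT2G39090, PAO1, PREP2, AT1G68190, DIC3, PPCK1, PPCK2, RP1, GPT1, SEX1, GDH2, PPH and ANL2.

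Interaction adjusted p values (edgeR) were 6.09e-09 for AT1G67480, 6.76e-09 for NHO1, 7.16e-09 for AT2G39090, and 1.43e-08 for PAO1, BAM9 and PREP2. In the CAM carbon cycle they were 1.49e-05 for PPC1, 8.15e-06 for PPC2, 7.80e-07 for PPCK1, 1.46e-07 for PPCK2, 8.12e-06 for PPT2, 0.00739 for PPT1, 9.53e-08 for RP1 and 0.00304 for GPT1. They were 0.0107 for NADP-ME1, 0.00446 for NADP-ME2, 0.0117 for NADP-ME4, 0.000124 for NAD-ME1, 0.00235 for ALMT6 and 0.00244 for BASS2. RP1 was higher in CAM at ED (1.08) and lower at MN (-1.02) and EN (-1.27), and GPT1 was higher at MD (1.29) and lower at ED (-1.998). At MD the call of GPT1 was lost without any 1 of CAM MD replicates 1, 2 and 3 and reC3 MD replicate 2 (adjusted p = 0.0506 to 0.0721, edgeR), and GPT1 was at 2.09 without reC3 MD replicate 3.

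PPC1, PPC2 and PPDK lay far apart in the 3 reC3 libraries at EN, with PPC1 at 0.220, 1.07 and 0.567 of its CAM mean in replicates 1, 2 and 3. A swap or a mixture with RNA of drought-stressed leaves is argued against by 34 other genes. These were at least 4-fold higher in CAM at MD, ED and MN. Their median share of the CAM level at EN was 0.0380, 0.104 and 0.0564 in replicates 1, 2 and 3. The medians rank the replicates in the same order as PPC1, but lie far below its shares. Another sampling time remains open. Along the change of 22 clock genes from MN to EN, replicate 2 lay 0.937 h (SE 0.390) later than replicate 1. Replicate 3 lay 0.770 h (SE 0.277) later than replicate 1. These errors, taken over genes with single libraries compared, leave a shift of 1 h undecided. The hours also take the genes to change steadily from MN to EN, which came from separate sets of libraries. A different pace of the return to C3 in single plants may also account for the spread but was not tested, as the labels give no measure of it.

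Light reaction genes were lower in CAM at EN (27 of 31, median log2 fold change -1.75). Replicate 1 of reC3 EN is argued against as the whole cause, since 22 were lower without it (median -1.12), and so is scaling, with 26 lower under library totals alone (median -1.36). Later sampling of reC3 relative to dawn as the only cause is left undecided. Relative to CAM, reC3 light reaction genes had moved 0.585 (SE 0.0677) of the way from EN to MD and clock genes 0.150 (SE 0.0566). The difference was 0.435 (SE 0.0883). These errors were taken over genes from group means. They leave out the spread between libraries and treat genes as independent (estimated correlation among light reaction genes 0.796). That test takes both groups of genes to change in proportion between EN and MD, which came from separate sets of libraries. No time between EN and MD was sampled. An earlier or stronger pre-dawn rise of these genes in re-watered leaves is therefore a hypothesis found and tested on the same data, and a contribution of sampling time may remain.

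Named paralogs moved together in part: in 18 pairs of best matches the SD over 24 libraries of the log2 ratio had a median of 0.480 (bootstrap 95% interval 0.273 to 0.863), against 0.506 in all 2210 best-match pairs, 708 of them under the 1st percentile of random pairs, and 0.947 in random pairs. Reads shared between paralogs cannot be told apart from separate genes here, since the interval spans the 1st and 5th percentiles of random pairs (0.306 and 0.413) and the 5th percentile of light reaction pairs that are not best matches (0.533), to which the median of the named pairs had a ratio of 0.901. Under the 1st percentile of random pairs lay 5 pairs, TPS9 with TPS10 (0.129), PPC1 with PPC2 (0.134), NIA1 with NIA2 (0.138), IRX1 with IRX5 (0.200) and ALMT4 with ALMT6 (0.228), and above the random median lay 5 others, AT4G26288 with OXS3 (0.990), PPT1 with PPT2 (1.19), SEX1 with PWD (1.74), LNK1 with LNK2 (2.01) and PRR3 with TOC1 (4.17). For PPC1 and PPC2 a fixed split of 1 transcript is argued against, since the log2 ratio of their counts was lower in CAM at all 4 times, with a mean difference of -0.19 (SE 0.0195, two-sided permutation test of mode within time, p = 6e-05), for example 0.47 ± 0.0069 in CAM and 0.71 ± 0.066 in reC3 at MD (SD, 3 libraries each). Several transcripts sharing both identifiers may still account for their joint changes.

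Other splits of the libraries were fitted for each count of changed genes. For the average over times, 1 of 100 splits, the real one, gave as many genes (9112, highest other 2502), and chance can be excluded. The same held for differences between times in CAM (10958, highest other 5987) and in reC3 (10220, highest other 5094). For the interaction the real split also gave the most genes (6583, highest other 5217). Chance cannot be excluded there, since permuting mode within each time also removes the difference between modes itself. Absence of an interaction alone was not tested. Other splits of all 24 libraries called many genes. Permuted labels may carry the large differences between modes or times into the tested contrast, but this was not tested. For 3 against 3 libraries the 10 splits are too few for a share under 0.05. With these 6 libraries alone the real split and the highest other gave 5527 and 0 genes at MD, 6719 and 0 at ED, 6249 and 0 at MN, 5050 and 0 at EN, 7649 and 0 for MN minus MD in CAM, 6010 and 0 in reC3, 8819 and 0 for EN minus ED in CAM, and 6414 and 0 in reC3 (edgeR).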

How the results depend on the processing

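Scaling by library totals alone, leaving out reC3 MD replicate 3 with reC3 EN replicate 1, and leaving out EN were chosen only after the data had been seen. Of 209 counts of changed genes under other settings, 199 lay within 1.5 times the reported count. The other 10 came from adjusted p under 0.01 with a 2-fold change, by construction stricter: 2817 genes at MD, 2838 at ED, 2243 at MN, 3764 at EN, 2659 in the average, 4206 in the interaction (adjusted p alone), 3629 for MN minus MD in CAM and 2567 in reC3, and 5502 for EN minus ED in CAM and 4679 in reC3. DESeq2 called 9123 genes in the average and 7107 in the interaction. Leaving out each library in turn gave 5253 to 5872 genes at MD, 5289 to 5938 at ED, 4372 to 5085 at MN, 6680 to 7660 at EN, 8905 to 9335 in the average, 5943 to 7191 in the interaction, 10468 to 10812 between times in CAM and 9679 to 10495 in reC3, 6495 to 6847 for MN minus MD in CAM and 4948 to 5730 in reC3, and 8315 to 8677 for EN minus ED in CAM and 7426 to 8083 in reC3. Near-even splits of higher and lower genes turned under some settings. The average turned to 4567 higher and 4555 lower with the replicate block. Without reC3 EN replicate 1 it turned to 4732 and 4603, and without reC3 EN replicate 2 to 4638 and 4611. It also turned to 4717 and 4566 without reC3 MD replicate 3 and reC3 EN replicate 1, and to 4710 and 4324 without EN. MN turned to 2558 and 2527 without CAM MN replicate 2. Under RLE scaling MN minus MD turned to 3693 and 3619 in CAM and to 2871 and 3196 in reC3, and EN minus ED in CAM to 4666 and 4350. With DESeq2 these were 3713 and 3633, 2901 and 3217, and 4687 and 4355. Without CAM MN replicate 2, MN minus MD in CAM turned to 3751 and 3096. MD turned to 2738 and 2761 without CAM MD replicate 2. EN minus ED in reC3 turned to 3980 and 4103 without reC3 EN replicate 1 and to 4086 and 4090 with the replicate block. Other turns, as of MN minus MD in reC3 with single libraries left out, are not listed.

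Of the gene lists, 4 were past the threshold in the average, 0 with an estimated correlation (camera, 2 at an unadjusted p under 0.05), 7 with RLE scaling, 7 with the replicate block, 8 without reC3 MD replicate 3 and reC3 EN replicate 1 and 4 to 7 with each library left out. The lists gained were the CAM carbon cycle, ABA and light reactions, plus epidermis markers without these libraries (adjusted p = 0.0486, camera; 0.0607 as reported); the cause was not tested. Of 177 results for named genes, 29 were lost under some setting, all 29 under the stricter threshold. Without EN, RP1 turned to 0.036 (adjusted p = 0.684) and GDH2 to -0.23 (adjusted p = 0.0140, edgeR), the averages of the 3 other times, and RPI3 (-0.39, adjusted p = 0.0954), FDH (-0.14, adjusted p = 0.0930) and GPT1 (-0.64, adjusted p = 0.0930) were lost. GPT1 was also lost without reC3 MD replicate 3 and reC3 EN replicate 1 (-0.37, adjusted p = 0.158), without a filter on low counts (-0.56, adjusted p = 0.0590) and under library totals alone (-0.61, adjusted p = 0.0637).

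Over all contrasts replicate numbers did not pair the libraries. Same-numbered libraries of different groups had deviations correlated by -0.200 to 0.367, over 0.1 in 6 of 24 pairs. Of these pairs 9 of 24 were best with their own number. Between modes at MN, however, each CAM library was best with its own number (0.264, 0.0869 and 0.138). With the replicate block the counts were 6199 at MD, 6428 at ED, 5451 at MN, 7466 at EN, 9122 in the average and 6571 in the interaction. Between times they were 10947 in CAM and 10228 in reC3, 7324 and 6106 for MN minus MD, and 8990 and 8176 for EN minus ED. Summing over features per Arabidopsis gene was not run, as each identifier is listed once. At these depths a count of 0 in 1 library allows a level of up to 0.298 to 0.585 CPM (3 counts, TMM-scaled).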

Other observations

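The protein families described here, and their tests, were chosen only after the data had been seen. A family was the set of genes with the same short description in the deposited data, so members described in other words were left out. The 172 families with at least 8 tested genes were tested in the average over times with camera. With a preset correlation 38 passed at adjusted p under 0.05, 12 higher and 26 lower in CAM. With an estimated correlation 0 passed (lowest adjusted p 0.221, 21 families at an unadjusted p under 0.05). Class III peroxidases, secreted enzymes that act on cell walls, were lower in CAM for 29 of 32 genes and higher for 1 (median log2 fold change -2.38, adjusted p = 1.77e-09; adjusted p = 0.221 with an estimated correlation). AT4G21960 averaged 325 CPM in CAM and 3243 CPM in reC3 (-4.24 ± 0.162, SE) and AT5G05340 changed by -3.03. GDSL lipases were lower for 28 of 35 genes and higher for 3 (median -2.32, adjusted p = 2.92e-09; adjusted p = 0.259 with an estimated correlation), with AT2G04570 at -3.98 and AT3G53100 at -3.88. Leucine-rich repeat kinases were lower for 55 of 70 genes and higher for 5 (median -1.04, adjusted p = 4.50e-09; adjusted p = 0.259 with an estimated correlation).

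The NPH3 family, of which some members act in phototropism, was lower for 18 of 23 genes and higher for none (median -0.65, adjusted p = 0.000136; adjusted p = 0.221 with an estimated correlation), with AT1G52770 at -3.13. Histone genes were lower for 14 of 19 (median -0.35, adjusted p = 0.00809; adjusted p = 0.423 with an estimated correlation), with AT1G09200 at -0.93. Sugar transporters of the SWEET family were higher in CAM for 8 of 11 genes and lower for none (median 1.76, adjusted p = 0.000633; adjusted p = 0.221 with an estimated correlation). AT4G25010 rose by 3.61 ± 0.121, AT2G39060 by 2.69 ± 0.118, AT1G21460 by 2.59 ± 0.106 and SWEET11 by 1.76 ± 0.104. RNA-binding proteins with an RRM motif were higher for 46 of 76 genes and lower for 5, by a small median of 0.32 (adjusted p = 0.000633; adjusted p = 0.281 with an estimated correlation). In the average each of these 7 families kept its direction under RLE scaling and library totals alone. Scaling hardly moved the median of all genes there (0.0137 with TMM, 0.0076 with RLE, 0.0073 with library totals). Keeping a direction was therefore a weak check, and families were not tested at single times. Members of a family are paralogs and can share reads, so their number of independent changes is uncertain.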
